A study of Homo sapiens with 16 samples.

How the data were processed

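Several kinds of libraries were analysed: QuantSeq 3' RNA libraries of a 4-day course of endoderm differentiation, guide sequences amplified from genomic DNA of definitive endoderm, and Drop-seq libraries of hepatic endoderm, all from H1 cells with doxycycline-inducible dCas9-KRAB. Per the labels' protocols, each guide was introduced with its own lentivirus, cells were selected with puromycin for 72 h, pooled and given doxycycline at 500 ng/mL from 48 h before differentiation on. QuantSeq used Lexogen's forward kit, which reads RNA 3' ends; hepatic endoderm cells were processed by version 3.1 of the Drop-seq protocol; guide amplification followed Datlinger and colleagues, all per the labels.

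The deposited counts per gene and library of the time course are whole read counts that were not normalized, per the file headers and the values. The deposited counts of hepatic endoderm are whole UMI counts per gene and cell barcode, with guide sequences listed as rows beside genes, per the file headers. The deposited counts of the genomic DNA libraries are whole read counts per guide, per the values. Per the submitters' processing notes, the series used build hg19 with HISAT2 2.0.5, Cell Ranger 2.1.0, STAR 2.4.2, Picard 1.96 and SAMtools 1.3; the notes used here give these tools no roles. The program that counted reads per gene or guide, the annotation and the guide sequences are not given in the sources used here. The deposited hepatic endoderm matrices already hold selected barcodes, each with at least 1006 genes in replicate 1 and 1011 in replicate 2, and no further cell filter or doublet caller was applied. Guide reads carry no molecular identifiers, so intervals and floors of guide shares cover counting error only. Genes are named by the symbols in the files, with the chromosome where the files give it.

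Samples were grouped by their titles. Column names tied 7 columns of the time course table to libraries with the control guide; 1 further column of per-sample values matched no label and was not used in any step. The design assumed 8 libraries, and 7 entered the fit, with 1 on day 3. Mitochondrial transcripts were not analysed here. Before libraries were averaged, replicates were compared: log2 CPM correlated at 0.964, 0.983 and 0.963 on days 0, 1 and 2, with a chi-square per degree of freedom of 4.57, 3.67 and 2.68, so each pair differed by more than counting error and was counted as 2 samples. In hepatic endoderm the chi-square per degree of freedom was 1.46 between the control-guide sums and 1.79 between the FOXA2-guide sums.

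For the time course, edgeR 4.0.16 with TMM scaling was run in R 4.3.3 on 13799 of 26252 genes kept by filterByExpr. Its quasi-likelihood test, in 1 fit of all 7 libraries without a replicate block, compared consecutive days, day 3 with day 0, and all days together; 6391 genes (46.3%) differed over all days. p-values were adjusted by the Benjamini-Hochberg method at 0.05. CPM values are those of edgeR, scaled by the TMM library size of the tested genes; means are given ± SD, and log2 fold changes come from the fit. The common biological coefficient of variation was 0.117 and the prior degrees of freedom 9.93. On simulated counts for day 2 against day 1 with 13799 genes, 60% of genes changed 2-fold and 98% of those changed 4-fold were recovered, and 5.39% of calls were false. Genes below a minimum mean CPM were never among the changed ones, so these rates do not cover them.

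Before the data were examined, 17 gene lists were fixed (pluripotency, primitive streak, definitive endoderm, NODAL and TGF-beta signalling, WNT targets, epithelial, mesenchymal, mesoderm, neural ectoderm, extraembryonic, endothelial and blood, hepatic, foregut with pancreas and gut, cell cycle, stress and immediate-early, cholesterol synthesis, glycolysis), as were the tests, the alternatives and the rule for named genes. Some genes belong to more than 1 list. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and, as an alternative, with an estimated correlation, adjusted over lists. The alternative also rests on the few residual degrees of freedom, so a list that it loses need not hold correlated genes. The rule named, for day 3 against day 0, the 10 higher and 10 lower genes with the largest log2 fold change among those that passed, had at least 20 CPM in the higher day and replicates of the days apart; likewise 6 and 6 for consecutive days. It further named up to 4 members of each list with the smallest adjusted p, members against the majority, and a fixed set of stem cell and endoderm genes; for guides, the 5 most and 5 least abundant guides and targets and the controls; for hepatic endoderm, the targeted gene and up to 6 higher and 6 lower genes with the smallest adjusted p. Some genes that the rule named are not reported here. Genes with 1 to 3 counts on a side are given as ratios of counts with a 95% exact interval, and a gene with 0 counts as a bound against a floor of 3 counts over the group.

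Each guide's share is its percent of all guide counts in a library, with Wilson 95% intervals computed per library. Per target, the mean log2 share of its detected guides over both replicates was compared with the 10 control guides by an exact two-sided permutation test over guides (286 splits for 3 guides, 66 for 2), adjusted over 50 targets. Shares of 40 targets rest on 3 guides and those of 10 on 2. In simulated shares of 150 guides, all guides had the spread of the control guides, and 10 targets of 3 guides were shifted up by 2 on the log2 scale. All 10 of these and 0 unshifted targets were called. Guides of some targets spread more widely in the data, with an SD of log2 share of 3.48 for OTX2 and 3.22 for NFYB. The simulation therefore gives no recovery rate for such targets, for targets with 2 guides or for lower shares.

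Cells of hepatic endoderm were assigned to a guide when they had at least 1 guide UMI and all guide UMIs came from that guide. Raw UMIs were summed per guide and replicate, guides with at least 10 cells in each replicate were kept, and the sums were tested with edgeR with the replicate as a block, since cells of both guides shared each pooled library. Of 9866 genes simulated for this comparison, 48% of those changed 1.5-fold and 99% of those changed 3-fold were recovered, and 6.37% of calls were false. The changed genes were drawn only from those above a minimum mean CPM, so recovery of scarcer genes was not measured. Among called genes 99.7% had the same sign in both replicates, which follows in part from calling them on these same replicates. Over all 9866 genes tested, called or not, log2 ratios of the replicates correlated at 0.811. Cells were clustered with the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 1 on 20 principal components of 2000 variable genes with 15 neighbours; a cluster was named only with at least 3 markers of a class among its leading genes. For shares of cells, each cell was thinned to 3000 UMIs, which 944 cells reached; these shares carry exact 95% intervals. List medians are also given with genes of 3 or fewer UMIs in a group held at 3.

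Alternatives were DESeq2 1.42.0, RLE size factors, other low-count filters, a replicate block, a test against a fold of 2 (glmTreat), fits of only the 2 days compared, each library left out in turn, other guide calls and other clustering settings. Sums thinned to equal depth, control-guide cells matched to FOXA2-guide cells within 10% in UMIs per cell, and lists without day 0 replicate 1 were added after the data had been seen. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps.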

Results

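The study followed human embryonic stem cells of the H1 line as they were differentiated to definitive endoderm, the embryonic layer that forms liver, pancreas and gut, and further to hepatic endoderm. The cells carried a doxycycline-inducible dCas9-KRAB, a DNA-binding protein without cutting activity fused to a repressor domain, which lowers transcription of the gene that its guide RNA points to. Genes are placed on build hg19 by chromosome alone. The series lists 16 samples in 8 groups of 2. Analysed here were 7 QuantSeq libraries, which count 3' ends of polyadenylated RNA, from cells with control guide 1 on days 0, 1, 2 and 3; 2 libraries of guide sequences amplified from genomic DNA of definitive endoderm; and 2 Drop-seq single-cell libraries of hepatic endoderm. The single-cell and guide amplicon libraries of definitive endoderm, 4 samples, and replicate 2 of day 3 were not analysed here. QuantSeq totals were 15335503 and 1901872 counts on day 0, 4824683 and 3896835 on day 1, 2081384 and 1662221 on day 2, and 6968236 in the single day 3 library. The guide libraries held 2241512 and 2364178 counts, and the hepatic endoderm libraries 5314390 and 4678011 UMIs (unique molecular identifiers). The labels do not say whether replicates came from separate cultures, so the spread between these samples may be technical. p-values of the time course measure only that spread, pooled over days and genes. In hepatic endoderm the spread is taken from other genes. Tests of guide shares measure the spread between guides, and tests over genes or targets the spread between those.

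The time course asks when genes change as cells with a control guide leave pluripotency. By day 1, transcripts of the primitive streak, the transient tissue through which mesoderm and endoderm form, were higher. T, on chromosome 6, which encodes brachyury, went from 0.558 ± 0.790 CPM (counts scaled to a common library size by edgeR) on day 0 to 39.5 ± 0.126 CPM on day 1 (SD, n = 2 each), a log2 fold change of 5.31 with an SE of 0.40 (edgeR adjusted p = 3.08e-06). EOMES and MIXL1, transcription factors of streak and early endoderm, rose from 60.8 ± 76.7 to 904 ± 43.3 CPM and from 68.7 ± 79.5 to 1022 ± 221 CPM. In all, 9 of the 11 measured primitive streak genes rose and none fell over all genes tested, and 9 rose and 1 fell adjusted over the list alone. WNT3 was among them at 3.49 and EVX1 at 5.29 on the log2 scale, whereas LHX1, at −0.68, did not pass. WNT target genes followed, with 8 of 13 higher and none lower over all genes, and 10 higher and 2 lower adjusted over the list alone. DKK4 (3.62), APCDD1 (2.20) and AXIN2 (1.37), all feedback inhibitors of WNT signalling, were among them. The 6 genes with the largest rises by the rule fixed in advance were T, FGF1 (5.15), SEZ6L (4.80), GAD1 (3.98), EGR1 (3.94) and SP5 (3.89); FGF1 encodes a fibroblast growth factor and EGR1 an immediate-early transcription factor. The camera set test gave an adjusted p of 6.04e-14 for the streak list and 6.57e-07 for the WNT list; with an estimated correlation both adjusted p values were 0.0771.

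Over the same day, part of the pluripotency program and 2 metabolic groups fell. Of 16 pluripotency genes 10 fell and 2 rose, the same counts adjusted over the list alone. PODXL, a surface sialomucin, fell by 3.13 on the log2 scale, and SOX2 went from 213 ± 54.2 to 39.0 ± 4.54 CPM (SD, n = 2 each). POU5F1, at 8133 ± 41.9 and 8666 ± 1059 CPM, and NANOG, at 258 ± 19.1 and 242 ± 7.57 CPM, did not pass the test. TDGF1, a NODAL co-receptor, and GDF3 went against the majority at 0.88 and 1.62. Of 12 cholesterol synthesis genes 11 fell, among them INSIG1 (−1.85) and HMGCS1 (−1.59). Of 13 glycolysis genes 12 fell, among them ALDOC (−2.22), HK2 (−1.96) and PGK1 (−1.85), while GAPDH, at −0.43, did not pass. Adjusted over the list alone, the counts for both metabolic lists were again 11 and 12. Camera adjusted p values were 3.18e-06 for pluripotency, 2.61e-11 for cholesterol synthesis and 8.99e-14 for glycolysis; with an estimated correlation the adjusted p values were 0.0776, 0.203 and 0.0647. The 6 lower genes named by the rule were INHBE (−5.04), SOX3 (−4.05), LINGO1 (−4.02), DDIT4 (−3.96), FGFBP3 (−3.92) and BTBD17 (−3.84); SOX3 encodes a transcription factor of neural and stem cells. Of 6 foregut, pancreas and gut genes 4 fell, ONECUT1 (−2.90), SOX2, HHEX (−1.87) and SOX9 (−1.78), and PROX1 (2.59) rose, over all genes and adjusted over the list alone (camera adjusted p = 0.0154; adjusted p = 0.203 with an estimated correlation). HHEX stood at −0.01 and did not pass without day 0 replicate 1.

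Definitive endoderm markers did not move together from day 0 to day 1: 2 of 19 rose and 7 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.438). The 2 day 0 libraries differed in these genes. SOX17 stood at 93.0 CPM in replicate 1 and 0 in replicate 2, GATA6 at 41.7 and 0 CPM, and CER1 at 700.2 and 27.2 CPM, against POU5F1 at 8163 and 8104 CPM. Of the 7 falls only that of CD177 (−2.76) also passed without day 0 replicate 1 (−2.78, edgeR adjusted p = 0.0488). CXCR4 went from −3.48 to −0.81, ERBB4 from −3.43 to −0.84 and HHEX from −1.87 to −0.01, and these 3 did not pass. Replicate 2 had 2 or fewer counts of SOX17 (−3.65), PRDM1 (−2.77), EPSTI1 (−2.93) and the endothelial gene VWF (−2.98), called lower with both libraries: without replicate 1 SOX17 passed as a rise (edgeR adjusted p = 0.00866), and the other 3 did not pass. Of 18 endoderm markers 8 then rose and 1 fell (camera adjusted p = 1.83e-06). The same library lowers the fold given for streak genes, since MIXL1 stood at 125 CPM in it and at 12.5 CPM in replicate 2, and EOMES at 115 and 6.52 CPM. Without it all 11 streak genes rose, with MIXL1 at 6.34, EOMES at 7.10 and NODAL at 4.64, and EGR1 stood at 6.07; T, WNT3, EVX1, SP5 and DKK4 had 2 or fewer counts left on day 0. Over all 13799 genes tested, edgeR called 1530 genes higher and 1840 lower on day 1 than on day 0 (24.4%), of which 518 and 1025 changed at least 2-fold by the estimate. DESeq2 called 1604, without SP5, HHEX, SOX17, PRDM1, EPSTI1 and VWF; of the calls above it kept 5 of 9 streak genes (T, MIXL1, EOMES, WNT3 and EVX1) and 1 of 9 endoderm markers (CD177). edgeR called 1739 genes without day 1 replicate 1 and 1869 without day 1 replicate 2, where the lone library is assumed to vary like the others.

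Between day 1 and day 2 the endoderm markers rose. SOX17, on chromosome 8, which encodes a transcription factor that specifies definitive endoderm, went from 4.63 ± 1.90 to 381 ± 47.1 CPM (SD, n = 2 each), a log2 fold change of 6.39 with an SE of 0.89 (edgeR adjusted p = 0.000343). FOXA2, on chromosome 20, which encodes a forkhead factor that opens chromatin in endoderm, went from 33.6 ± 0.607 to 272 ± 23.3 CPM, and GATA6, a zinc-finger factor of endoderm, from 17.2 ± 2.35 to 176 ± 32.8 CPM. Of 19 endoderm markers 12 rose and none fell, and 14 rose adjusted over the list alone; the surface receptor CXCR4 (5.25), PRDM1 (4.91) and HHEX (4.43) were among them, and FOXA3 (−0.18) did not pass. Cholesterol synthesis genes moved back, with 10 of 12 higher and none lower in both counts, among them DHCR7 (1.86), LSS (1.72) and INSIG1 (1.67), while SC5D (0.08) and FDFT1 (0.09) did not pass. Pluripotency genes moved both ways, with 7 of 16 lower, such as POU5F1 (−1.55) and NANOG (−1.01), and 4 higher, such as PODXL (1.59); 8 fell and 4 rose adjusted over the list alone. T fell by 3.72 and WNT3 by 1.03 on the log2 scale, while LHX1 rose by 3.89, so that 3 of 11 streak genes rose and 4 fell (camera adjusted p = 0.125).

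Smaller groups also moved between days 1 and 2. Of 11 epithelial genes 4 rose, the keratins KRT8 (2.66), KRT19 (1.94) and KRT18 (1.45) and the claudin CLDN6 (1.56), and 1 fell, the E-cadherin gene CDH1 (−1.56). Of 8 mesenchymal genes 3 rose, VIM (2.06), COL1A1 (1.75) and the N-cadherin gene CDH2 (1.19), and SNAI1 fell by 1.00. Of 13 glycolysis genes 4 rose, LDHA, HK2, PKM (1.15) and the glucose transporter gene SLC2A3 (1.77). Of 14 stress and immediate-early genes 6 rose, such as ATF3 (2.37) and DDIT4 (2.05), and 4 fell, such as EGR1 (−2.38) and JUNB (−1.38). Of 20 cell cycle genes 5 fell, TOP2A (−1.11), CENPF (−0.66), PCNA, CCNB1 and CDK1, and all 3 measured extraembryonic genes rose: IGFBP3 (5.02), which encodes a secreted growth factor binding protein, and the transcription factors GATA3 (2.89) and TFAP2C (2.47). Adjusted over the list alone, the counts higher and lower were 6 and 3 for epithelial, 3 and 1 for mesenchymal, 6 and 0 for glycolysis, 8 and 4 for stress, 0 and 7 for cell cycle, and 3 and 0 for extraembryonic genes. Camera adjusted p values were 5.93e-11 for endoderm, 4.02e-17 for cholesterol synthesis, 0.0104 for pluripotency, 0.00437 for epithelial, 0.0282 for mesenchymal and for stress genes, 0.00493 for glycolysis and for cell cycle, and 5.66e-06 for extraembryonic genes. With an estimated correlation the adjusted p values ran from 0.235 for cholesterol synthesis to 0.479 for mesenchymal genes, with 0.293 for endoderm.

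Among single genes, LINC00261, a noncoding RNA gene beside FOXA2, had 2 counts over both day 1 libraries and rose 127-fold by the ratio of counts (95% exact interval 34.3 to 1060). GDNF, a neurotrophic factor gene with 3 counts on day 1, rose 96.3-fold (32.2 to 473), and PRSS1, a trypsinogen gene with near-identical copies and so uncertain, 116.5-fold from 2 counts (31.4 to 975). DIO3, which encodes an enzyme that inactivates thyroid hormone, rose by 5.86 and the natriuretic peptide gene NPPB by 5.70 on the log2 scale. In the other direction, SEZ6L fell to 2 counts over both day 2 libraries, a 65.7-fold ratio (18.0 to 545), and PLEKHH2 (−5.23), FGF1 (−4.93), LRAT (−4.50) and DACT1 (−4.33) fell; LRAT encodes an enzyme that esterifies retinol, and DACT1 a modulator of WNT signalling. The intervals cover counting error only. edgeR called 1229 genes higher and 911 lower on day 2 than on day 1 (15.5% of those tested), of which 702 and 478 changed at least 2-fold by the estimate. DESeq2 called 1245 and passed none of SOX17, FOXA2, GATA6, CER1, PRDM1, WNT3, CDH2, SNAI1, GATA3 and EGR1. Both programs were fitted to all days with 1 spread per gene, so the unlike day 0 libraries enter this comparison too. SOX17, for example, stood at 3.28 and 5.97 CPM on day 1 and at 414.65 and 347.98 CPM on day 2. On day 0 it stood at 93.03 and 0 CPM. How far this accounts for the calls that DESeq2 did not make was not tested. DESeq2 kept 4 of 12 endoderm calls (CXCR4, HHEX, CD177 and KLF5), 3 of 7 streak calls (T, LHX1 and EVX1) and 2 of 5 cell cycle calls (TOP2A and CENPF). Without each library of these days in turn, where CER1, WNT3, CDH2 and GATA3 did not pass, edgeR called 1056 and 1271 genes (day 1 replicates 1 and 2) and 954 and 1341 (day 2 replicates 1 and 2); SNAI1, JUNB and CLDN6 did not pass without at least 1 of these libraries.

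Between day 2 and day 3 few genes passed. LEFTY2, which encodes a secreted NODAL antagonist, went from 156 ± 24.8 CPM (SD, n = 2) to 1463 CPM (n = 1), a log2 fold change of 3.23 with an SE of 0.60 (edgeR adjusted p = 0.0247). The forkhead gene FOXQ1 (3.26), the titin gene TTN (3.13), EPSTI1 (3.11), the receptor gene ERBB4 (2.99) and AJAP1 (2.98) rose as well, and CXCR4 went from 94.9 ± 29.0 to 482 CPM. The WNT inhibitor gene DKK4 went from 84.8 ± 22.6 to 15.9 CPM, and IGFBP3 (−2.68), the chemokine gene CXCL14 (−2.09), the KIT ligand gene KITLG (−1.94) and SNAR-C4 (−1.75) fell; SNAR-C4 belongs to a family of near-identical copies, which leaves its count uncertain. POU5F1 fell by a further 1.09 and CDH1 by 1.48. Of 20 cell cycle genes only UBE2C (−0.91) fell over all genes tested, while 18 fell adjusted over the list alone (camera adjusted p = 1.45e-13; adjusted p = 0.0587 with an estimated correlation).

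Of 19 endoderm markers 3 rose from day 2 to day 3 (CXCR4, EPSTI1 and ERBB4), with 4 higher and 1 lower adjusted over the list alone. Of 18 genes of NODAL and TGF-beta signalling 2 rose, LEFTY2 and the signal transducer SMAD2 (0.79), and 4 adjusted over the list alone. Of 14 stress genes 3 rose, DDIT4, from 54.9 ± 13.2 to 165 CPM, GADD45A (1.36) and DDIT3 (1.29), and 4 adjusted over the list alone. Camera adjusted p values were 0.00348, 0.00104 and 0.00722 for these lists, and 0.856, 0.823 and 0.823 with an estimated correlation. With the replicate block the endoderm list did not pass, while the NODAL and stress lists did. edgeR called 106 genes higher and 47 lower on day 3 than on day 2 (1.11%), with 2014 at an unadjusted p under 0.05. The single day 3 library is assumed to vary like the others; DESeq2 called 96 genes (58.3% of them higher against 69.3% with edgeR) and edgeR 799 from the libraries of these days alone and 711 with no filter on low counts. edgeR called 551 without day 0 replicate 1, 555 without day 0 replicate 2, 74 without day 2 replicate 1 and 15 without day 2 replicate 2. LEFTY2, EPSTI1, ERBB4, CXCR4, DDIT3 and GADD45A did not pass with DESeq2 or without either day 2 library, while FOXQ1, SNAR-C4, POU5F1 and DDIT4 did; IGFBP3, DKK4, CXCL14, KITLG, CDH1, SMAD2 and UBE2C did not pass without day 2 replicate 2.

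**Figure D1:**
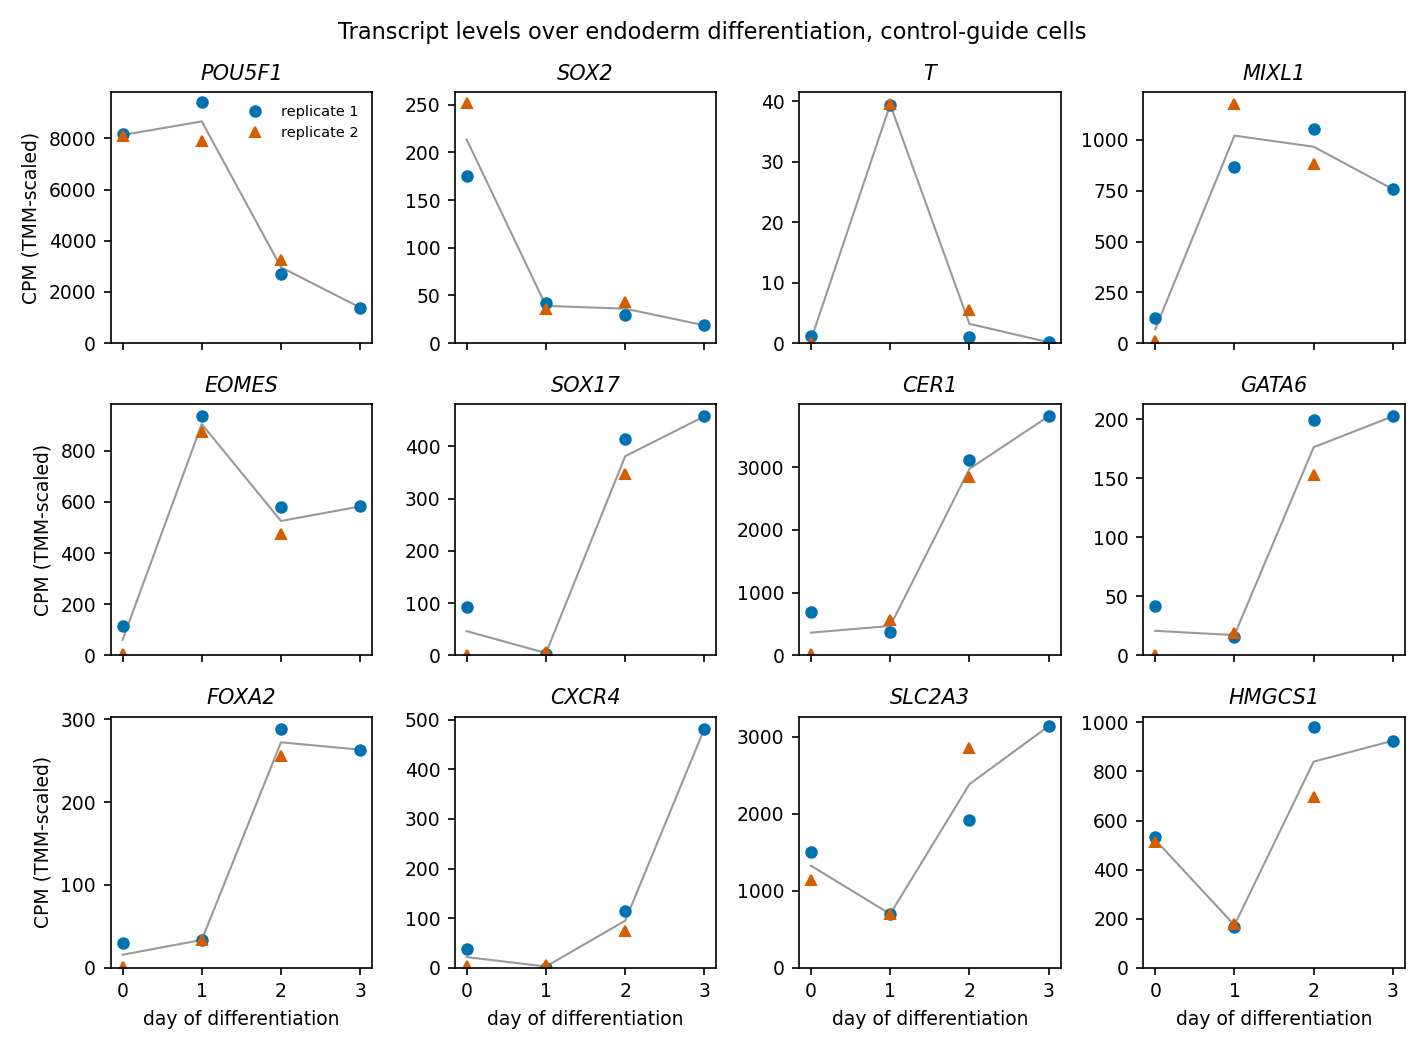
CPM of 12 genes (vertical axes, each on its own linear scale from 0) against day of differentiation (horizontal axes); points are libraries, 2 per day and 1 on day 3, and the grey line joins the means. T peaks on day 1 at 39.5 CPM, SOX17 stays under 10 CPM on day 1 and reaches 458 CPM on day 3, and day 0 replicate 1 lies above replicate 2 for SOX17, CER1, GATA6, FOXA2, MIXL1 and EOMES.

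Across the whole course, day 3 cells differed from day 0 cells in 5071 genes, 2675 higher and 2396 lower (36.7% of 13799 tested by edgeR), of which 1438 and 1536 changed at least 2-fold by the estimate. Of 19 endoderm markers 16 rose and none fell, the same counts adjusted over the list alone. FOXA2 went from 15.8 ± 20.8 CPM (SD, n = 2) to 263 CPM (n = 1), CXCR4 from 21.6 ± 24.4 to 482 CPM, CER1 from 364 ± 476 to 3810 CPM and SOX17 from 46.5 ± 65.8 to 458 CPM. GATA4 (2.64), GATA6 (2.82) and HHEX (3.01) also rose, and FOXA3 and CD177 were among those that did not pass. Of 16 pluripotency genes 9 fell in both counts, such as SOX2 (−3.49), USP44 (−3.16), POU5F1 (−2.55) and NANOG (−1.19), and TDGF1 (1.37) and SALL4 (1.22) rose. Of 11 streak genes 8 rose, among them LHX1 (3.34), MIXL1 (3.29), GSC (3.16) and EOMES (3.05), and T, at 0.145 CPM on day 3, did not pass. Of the 18 NODAL and TGF-beta genes 8 rose, LEFTY2 (3.66) and NODAL (3.05) among them, and 9 adjusted over the list alone; FOXH1 (−0.32) and SMAD4 (−0.14) did not pass. The spread between the day 0 libraries enters all of these folds. Without day 0 replicate 1, 16 of 18 endoderm markers rose and none fell, and folds were larger: CER1 stood at 7.12, CXCR4 at 6.77, GSC at 6.51, EOMES at 6.46, LHX1 at 6.40, NODAL at 6.34, LEFTY2 at 6.09, MIXL1 at 5.90 and HHEX at 4.87. SOX17, GATA4, GATA6 and FOXA2 had 2 or fewer counts left on day 0.

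The other lists were as follows for day 3 against day 0. Among 8 mesenchymal genes 5 rose, TWIST1 (3.52), ZEB1 (2.97), CDH2 (2.64), FN1 (1.85) and VIM (1.38); TWIST1 did not pass with DESeq2. Day 0 replicate 2 had 1 count of ZEB1 and 0 of TWIST1, and CDH2 stood at 280 and 77.7 CPM in day 0 replicates 1 and 2. Without replicate 1 CDH2 stood at 3.89, FN1 at 2.16 and VIM at 1.83. Among 13 WNT targets 6 rose, and 7 adjusted over the list alone, with APCDD1 at 1.31. Among 14 stress genes 11 rose, such as GADD45B (1.98) and PPP1R15A (1.73). Among 20 cell cycle genes 13 fell, and 14 adjusted over the list alone, such as TOP2A (−1.61) and CDK1 (−1.25). Among 13 glycolysis genes 9 fell, such as ENO2 (−2.41) and PGK1 (−1.65), while SLC2A3 (1.24) and PKM (0.94) rose. Camera adjusted p values were 1.78e-07 for endoderm, 8.69e-07 for pluripotency, 0.000159 for streak and for stress genes, 0.000953 for NODAL and TGF-beta, 0.000288 for mesenchymal and for glycolysis genes, 0.0103 for WNT targets and 7.17e-05 for cell cycle. With an estimated correlation the adjusted p values lay between 0.128 and 0.337. Epithelial genes went both ways, with KRT19 (1.81) and KRT18 (0.99) among 5 of 11 higher and CDH1 (−3.20) among 4 lower, as did cholesterol synthesis genes, with 6 of 12 higher, such as DHCR7 (1.16), and SC5D (−1.03) lower.

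Few markers of other lineages had enough counts to be tested. Of 5 measured mesoderm genes 2 rose, FOXC1 (2.12) and BMP4 (1.49), and 2 fell, KDR (−3.96) and MESP2 (−2.27); the median of this list was positive, its mean and the camera direction negative. Of 5 neural ectoderm genes SIX3 (2.60) and SOX10 (2.14) rose and SOX3 (−2.14) and DCX (−0.87) fell. GATA3 (2.12) and TFAP2C (1.08) were the 2 of 3 extraembryonic genes that rose. Of 3 endothelial and blood genes VWF (2.42) rose and ERG, with 2 counts on day 3, fell. Of 3 hepatic genes APOA2 (3.67) rose, to 8.97 CPM, and AMBP (−1.93) fell. Of 6 foregut, pancreas and gut genes HHEX rose and ONECUT1 (−3.43), SOX2 and SOX9 (−3.16) fell. The camera adjusted p values of these lists, and of the epithelial and cholesterol lists, were above 0.05, the lowest being 0.0527 for the extraembryonic list. With RLE size factors the extraembryonic list lay just below 0.05. Adjusted over the list alone, the counts higher and lower were 6 and 4 for epithelial, 3 and 0 for extraembryonic and 1 and 2 for endothelial and blood genes, and for the other lists the same as over all genes where no second count is given. MESP2, BMP4, SOX10, DCX, GATA3, VWF, ERG and AMBP did not pass with DESeq2, nor SOX10 (1.68), DCX (−0.76) and AMBP (−2.35) without day 0 replicate 1 and BMP4 and AMBP without day 0 replicate 2. Without day 0 replicate 1 FOXC1 stood at 3.28, and BMP4, SIX3, GATA3, VWF and APOA2 had 2 or fewer counts left on day 0.

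The 10 genes with the largest rise from day 0 to day 3 by the rule were SLC7A14 (4.20), CXCR4 (4.10), LINC00261 (3.79), LEFTY2 (3.66), FOXA2 (3.59), FOXQ1 (3.56), ANGPT2 (3.53), HAS2 (3.44), CHRD (3.43) and ACKR3 (3.36). Day 0 replicate 2 had few counts of most of these, so their folds and order rest on replicate 1. Without it CXCR4 stood at 6.77, LEFTY2 at 6.09 and ACKR3 at 5.93, and the other 7 had 2 or fewer counts left on day 0. HAS2 encodes a hyaluronan synthase, CHRD the BMP antagonist chordin and ACKR3 a scavenging chemokine receptor. In the other direction, GDPD2 had 1 count on day 3, a 126.5-fold ratio (95% exact interval 22.5 to 5010), and PLA2G4C (−6.28), POU3F1 (−5.54), LINC00599 (−5.52), HMX2 (−5.47) and LECT1 (−5.38) fell. Metallothionein genes, which encode metal-binding proteins and lie together on chromosome 16, made up the rest: MT1F had 0 counts on day 3 and was at least 41.5-fold lower against a floor of 3 counts, and MT1G (−5.51), MT1E (−5.29) and MT1X (−5.24) fell. Counts of these near-identical copies are uncertain. DESeq2 called 2546 genes and did not pass SOX17, FOXA2, CER1, GATA4, GATA6, MIXL1, EOMES, GSC, LHX1, NODAL, ANGPT2 or ACKR3. It kept 6 of 16 endoderm calls, 1 of 8 streak calls (FGF8), 5 of 8 NODAL and TGF-beta calls (LEFTY1, LEFTY2, TDGF1, SMAD2 and SMAD3) and 3 of 11 stress calls (DDIT3, GADD45B and PPP1R15A).

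The genes that the screen targeted are not independent evidence of a direction, because the study chose them. Of 50 targets 49 were measured in the time course, USF1 being the exception, and 26 changed over the days by edgeR (14 by DESeq2). Of all 13799 genes tested by edgeR, 46.3% changed over the days, and from day 0 to day 3 2675 rose and 2396 fell. Of all 49 measured targets, changed or not, day 3 held the highest mean level for 23, against 8 on day 0 and 9 each on days 1 and 2. Day 3 is a single library, and these shares were not computed over all genes. From day 0 to day 3, 21 rose and 2 fell: ETV5 (−0.69) and NR5A2, which had 3 counts on day 3. GSC (3.16) was among those that rose, and SMAD4, FOXH1 and CTCF (−0.05) did not pass. GSC did not pass with DESeq2, and NR5A2 passed neither with it nor without day 0 replicate 1.

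The guide libraries compare the abundance of guides against each target with that of control guides in definitive endoderm. Guides against FOXH1, a DNA-binding partner of SMAD proteins, SMAD2, a transducer of NODAL and activin signals, and SOX17 were the most abundant. The 3 guides of FOXH1 stood 2.53 above the 10 control guides on the log2 scale and held 9.40% ± 0.0305 of all guide counts (SD, n = 2). Those of SMAD2 stood at 2.22 and held 7.44% ± 0.143, and those of SOX17 at 1.92 and 5.99% ± 0.0746. RREB1 (1.26) and MIXL1 (0.99) came next by the same measure. At the other end were CDC5L, a splicing factor gene, at −6.41 and 0.0202% ± 0.00216; MYBL2, a cell cycle transcription factor gene, at −5.78 and 0.0328% ± 0.0101; and EOMES at −5.13 and 0.0478% ± 0.0126. For these 8 targets all 3 guides lay on the same side of all 10 control guides, the smallest p that the exact two-sided permutation test can give with 3 guides (0.0035; adjusted p = 0.0146 over 50 targets).

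In all, 22 of 50 targets differed from the control guides after adjustment, 12 higher and 10 lower, and 27 had an unadjusted exact permutation p under 0.05. NFYB (−3.16) and OTX2 (−2.71) were the next lowest, each with 2 of 3 guides below all control guides (exact permutation test, adjusted p = 0.0361); without guides under 100 counts NFYB stood at −1.43 and did not pass. GATA6, with 2 detected guides, stood at −0.99 (exact permutation test, adjusted p = 0.0361). FOXA2 (0.29, adjusted p = 0.189), SMAD4 (−0.75, adjusted p = 0.126), GATA4 (0.16, adjusted p = 0.551) and GSC (−1.61, adjusted p = 0.258) did not pass the same exact permutation test. HSF2 and JUND, called higher, and ZNF410, called lower, were lost without a replicate, at values of 0.45 for HSF2 without replicate 1, 0.48 and 0.60 for JUND and −0.45 and −0.62 for ZNF410 without replicates 1 and 2. No starting pool was used here, so a share also holds the number of cells that entered the pool with each guide.

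The 5 most abundant guides were FOXH1 guide 3 (4.33% ± 0.106), SMAD2 guide 1 (2.82% ± 0.130), SMAD2 guide 2 (2.77% ± 0.0304), FOXH1 guide 2 (2.67% ± 0.0660) and FOXH1 guide 1 (2.398% ± 0.142; SD, n = 2 each). The 5 scarcest detected guides were CDC5L guide 2 (0.00342% ± 0.000344), OTX2 guide 1 (0.00514% ± 0.000685), MYBL2 guide 1 (0.00605% ± 0.00324), CDC5L guide 3 (0.00708% ± 0.00118) and NFYB guide 1 (0.00733% ± 0.00715). The 10 control guides held between 0.389% and 0.695% each, with a mean of 0.531% ± 0.0911 between guides, and together 5.24% (95% Wilson interval 5.21 to 5.27) and 5.38% (5.35 to 5.41) of the counts of replicates 1 and 2. Of the 160 guides, 10 had no count in either library, which allows shares of up to 0.000134% and 0.000127%: they were guides of ARNT, ATF3, CREB3, FOXA2, FOXA3, GATA4, GATA6, JUND, TGIF2 and ZNF263, 1 each. Across the 150 detected guides, which are not independent replicates, log2 shares of the libraries correlated at r = 0.984 and rho = 0.965. The libraries differed by more than counting error, with a chi-square of 116 per degree of freedom, so intervals from counts alone understate the error.

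**Figure D2:**
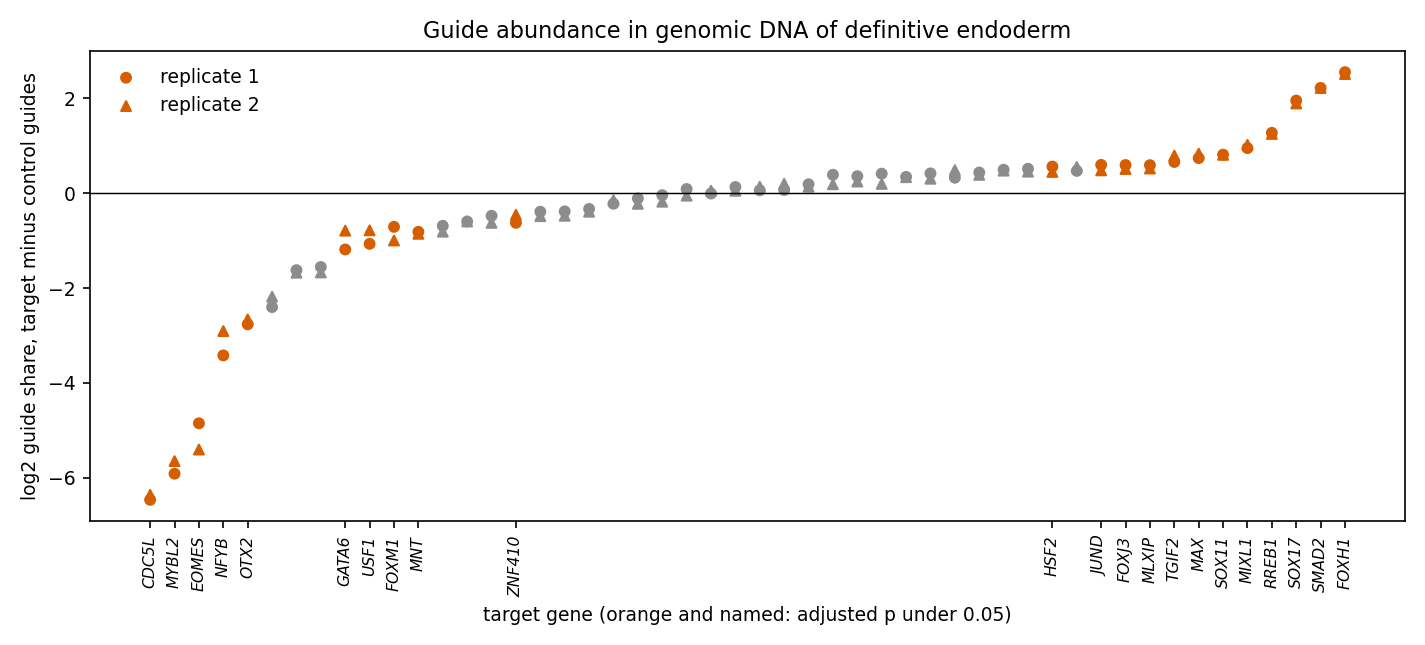
Mean log2 share of the guides of each of 50 targets minus that of the 10 control guides, in definitive endoderm genomic DNA; each point is a replicate, and orange marks targets with an adjusted permutation p under 0.05, which alone are named on the axis. FOXH1 lies at 2.55 and 2.51 and CDC5L at −6.47 and −6.36 in replicates 1 and 2.

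Hepatic endoderm cells expressed liver genes. The libraries held 589 and 576 cell barcodes with medians of 6865 and 6882 UMIs and 2944 and 2972 genes. MALAT1, a nuclear noncoding RNA, took 2.14% of UMIs in both, followed by TTR, which encodes a thyroid hormone carrier made by liver, with 0.60% and 0.587%, and APOA1, which encodes the main protein of high-density lipoprotein, with 0.575% in both; Wilson 95% intervals reached at most 0.0131 percentage points to either side. These intervals cover counting of UMIs only. The replicates differed by more for some genes, such as KRT19 (0.349 to 0.359 and 0.37 to 0.381), and not for others, such as APOA1. TMSB10, S100A10, FTL, RPS6, APLP2 and KRT19 were also among the 10 leading genes of both replicates, with RPLP1 in replicate 1 and AFP, the alpha-fetoprotein gene, in replicate 2. Log2 CPM of the replicates correlated at r = 0.990 across 12672 genes. Of 12 clusters, 2 had at least 3 hepatic markers among their leading genes: cluster 1, led by RBP4 and TF, with 13.8% (95% exact interval 11.1 to 16.8) and 13.9% (11.2 to 17.0) of cells of replicates 1 and 2, and cluster 7, led by ADH1B and HHEX, with 7.98% (5.92 to 10.5) and 7.99% (5.91 to 10.5). Cluster 7 also had 3 foregut markers among those genes, and the other 10 clusters stay unnamed.

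A guide UMI was found in 81.5% (95% exact interval 78.1 to 84.6) and 81.4% (78.0 to 84.5) of cells. Cells with a single guide held either FOXA2 guide 2 (88 and 92 cells) or control guide 1 (235 and 207 cells), which allows a comparison of FOXA2 repression with a control within each library. FOXA2 itself was lower: 9.21 ± 2.58 CPM in FOXA2-guide cells against 124 ± 9.60 CPM in control-guide cells (SD, n = 2 sums of cells each), a log2 fold change of −3.73 with an SE of 0.27 (edgeR adjusted p = 5.93e-40). Liver genes fell with it. AFP went from 5000 ± 159 to 67.0 ± 4.13 CPM, and TF, which encodes transferrin, from 864 ± 82.7 to 3.68 ± 3.46 CPM. DLK1 (−6.54), IGFBP3 (−5.27), the fibrinogen gene FGB (−4.54) and the apolipoprotein gene APOB (−4.13) were the other lower genes named by the rule; FGB differed between replicates, at −7.15 and −3.32. All 19 measured hepatic genes fell, over all genes and adjusted over the list alone, with a median of −4.37, or −3.83 with AHSG, ALB and APOC3, which had 3 or fewer UMIs left, held at a floor of 3. TTR (−4.41), APOA1 (−2.86), APOA2 (−3.81), SERPINA1 (−5.69), RBP4 (−4.80) and HNF4A (−2.10), a central liver transcription factor, were among them. Camera gave an adjusted p of 1.53e-83, and with an estimated correlation 0.708 with the replicate block and 0.101 without it. With the block this alternative has 1 residual degree of freedom and gave the same 0.708 for lists of 1 to 19 measured genes. It therefore cannot tell changed from unchanged lists. The rotation set test fry, without the block, gave an adjusted p of 0.0118.

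Other endoderm factors changed in both directions. Of 14 measured endoderm markers 10 fell, FOXA2 itself and 9 others, among them HHEX (−4.25), GATA6 (−2.54), FOXA3 (−2.24) and FOXA1 (−2.02). SOX17 (1.56), EPSTI1 (1.44) and OTX2 (0.72) were the 3 that rose. GATA4, at 99.9 ± 7.56 CPM with the control guide and 97.1 ± 15.9 with the FOXA2 guide, did not pass. The camera adjusted p, for the list with FOXA2 itself in it, was 0.00228, and with an estimated correlation 0.708 with the replicate block and 0.379 without it. The same 0.379 without the block was given to the foregut, pluripotency, epithelial and stress lists. At the preset correlation the camera adjusted p of these lists ran from 0.000661 to 0.0618. With so few sums the estimated correlation cannot tell these lists apart without the block either. All 4 foregut genes fell, HHEX, ONECUT1 and PROX1 among them, and ONECUT1 had 1 UMI left. Their camera adjusted p was 0.000661, and with an estimated correlation 0.708 with the block and 0.379 without it. The counts were the same adjusted over the list alone for both lists. The 6 higher genes named by the rule were the keratin gene KRT7 (6.67), SPP1 (6.61), which encodes osteopontin, the collagen gene COL1A2 (5.90), CALB2 (5.33), the myosin light chain gene MYL4 (4.18) and ANXA1 (3.98). SPP1 went from 14.3 ± 11.3 to 1334 ± 2.76 CPM and COL1A2 from 22.7 ± 1.36 to 1369 ± 169 CPM.

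In the NODAL and TGF-beta list 6 of 16 rose, TDGF1 (4.14) among them, with LEFTY2 at 49 UMIs against 3, and 8 fell, such as SMAD3 (−2.46); its median of −0.29 and mean of 0.21 differ in sign (camera adjusted p = 0.614). Of 10 pluripotency genes 5 rose, TDGF1 and LIN28A (1.02) among them, and 2 fell. Of 11 epithelial genes 5 rose, among them KRT18 (2.85) and KRT8 (1.93), and KRT19 (−1.04) and OCLN fell. The camera adjusted p was 0.0211, and with an estimated correlation 0.708 with the block and 0.379 without it. Of 13 stress genes 6 rose, among them TRIB3 (3.32) and DDIT4 (2.13), and none fell. Here the camera adjusted p was 0.0102, and with an estimated correlation 0.708 with the block and 0.379 without it. Cholesterol synthesis had 7 of 12 lower and SC5D (1.05) higher; glycolysis had SLC2A3 (−2.14) and ALDOC (−4.14) among 3 of 13 lower and 4 higher, with a median of 0.06 against a mean of −0.29. Of 20 cell cycle genes 5 rose by edgeR (CCNB1, MCM3, MCM5, PCNA and RRM2) and none fell; DESeq2 passed none of these 5, and CCNB1, MCM5 and PCNA did not pass with at least 2 guide UMIs (0.40, 0.74 and 0.48) or with control cells matched in UMIs per cell. In the matched cells MCM5 stood at 0.84 and PCNA at 0.57, against 0.80 and 0.53 with all cells, and CCNB1 at 0.32 against 0.51. Of 8 mesenchymal genes 4 rose, CDH2 (0.78), VIM (0.86), LUM (0.64) and COL3A1, and FN1 (−1.09) fell. COL3A1 went opposite ways in the replicates, from 13.2 to 1.2 CPM in replicate 1 and from 0 to 59.1 CPM in replicate 2, and did not pass without the replicate block (adjusted p = 0.0827) or with DESeq2 (adjusted p = 0.855). Mesoderm had BMP4 (2.44) higher and PDGFRA (−2.07) lower of 3; extraembryonic genes had KRT7 higher and IGFBP3 and PGF (−3.28) lower of 4; WNT targets had DKK1 (3.30) higher and AXIN2 (−1.70) and SP8 (−2.19) lower of 5. NODAL (1.36) was the 1 measured streak gene and rose, ZIC2 (−0.83) was the 1 neural gene and did not pass, and no endothelial or blood gene was measured. Camera adjusted p values of the lists without a value here lay between 0.0618 for pluripotency and 0.938 for WNT targets. Adjusted over the list alone the counts higher and lower were the same except for pluripotency (6 and 2), epithelial (5 and 3), cell cycle (4 and 0), stress (6 and 1), cholesterol synthesis (1 and 9), extraembryonic (1 and 3) and neural genes (0 and 1).

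Over all 9866 genes tested, edgeR called 1856 higher and 1854 lower with the FOXA2 guide (37.6%), 768 and 1033 of them at least 2-fold and 125 and 140 at least 8-fold by the estimate. The 4 sums leave 1 residual degree of freedom with the replicate block, so the spread is taken wholly from other genes (infinite prior degrees of freedom, against 13.8 without the block, where the adjusted p for FOXA2 was 1.27e-08). DESeq2 called 998 genes and ended, among others, the calls of FOXA1, FOXA3, SOX17, OTX2, OCLN, AXIN2, SP8 and the hepatic genes AHSG, APOC3 and FGG. It kept 7 of 13 endoderm calls, 6 of 14 NODAL and TGF-beta calls, 1 of 8 cholesterol synthesis calls (SC5D), 4 of 7 glycolysis calls (PFKP, ALDOC, ENO2 and SLC2A3), 3 of 7 pluripotency calls (ZFP42, TDGF1 and LIN28A), 4 of 7 epithelial calls (CLDN6, KRT8, KRT18 and KRT19), 3 of 5 mesenchymal calls (CDH2, VIM and FN1) and 1 of 3 WNT target calls (DKK1). Only 1 guide against FOXA2 had enough cells. Called FOXA2-guide cells held more UMIs than called control-guide cells, with medians of 8082 and 8306 against 5828 and 6234. The call left out 157 and 170 cells with more than 1 guide. With the top guide at 80% of guide UMIs, control-guide cells numbered 344 and 341 in place of 235 and 207. FOXA2-guide cells then numbered 107 and 103 in place of 88 and 92. Control-guide cells with FOXA2 guide 3, all left out, had medians of 16 and 12 control-guide UMIs, against 4 and 4 without it. How far the call made this depth gap was not tested.

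Lower levels of liver transcripts were seen in most cells with the FOXA2 guide. With each cell thinned to 3000 UMIs, hepatic genes took a median of 2.47% and 2.60% of UMIs in control-guide cells and 0.10% and 0.0667% in FOXA2-guide cells of replicates 1 and 2. Cells with under 1% made up 11.9% (95% exact interval 7.6 to 17.4) and 13.9% (9.05 to 20.2) of control-guide cells, and 96.1% (88.9 to 99.2) and 96.2% (89.4 to 99.2) of FOXA2-guide cells. An AFP UMI was found in 71.4% (64.3 to 77.7) and 67.9% (60.2 to 74.9) of thinned control-guide cells and in 10.5% (4.66 to 19.7) and 15% (8.0 to 24.7) of thinned FOXA2-guide cells. Without thinning the shares were 77.4% and 76.8%, and 26.1% and 33.7%. ACTC1, a cardiac actin gene chosen after its values were seen, went the other way, from 10.8% and 9.70% to 64.5% (52.7 to 75.1) and 68.8% (57.4 to 78.7). Cells with either guide also fell mostly in different clusters, which were drawn from the same counts. Clusters 3, 8 and 12 held 92, 51 and 25 FOXA2-guide cells and 4, 1 and 9 control-guide cells, while the hepatic clusters 1 and 7 held 0 FOXA2-guide cells and 85 and 35 control-guide cells. Thinning left out 50 and 42 control-guide cells and 12 and 12 FOXA2-guide cells that were shallower. Free RNA in droplets can add UMIs to cells that do not express a gene, and sampling misses transcripts in cells that do, so these are shares of detection and not of expressing cells.

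**Figure D3:**
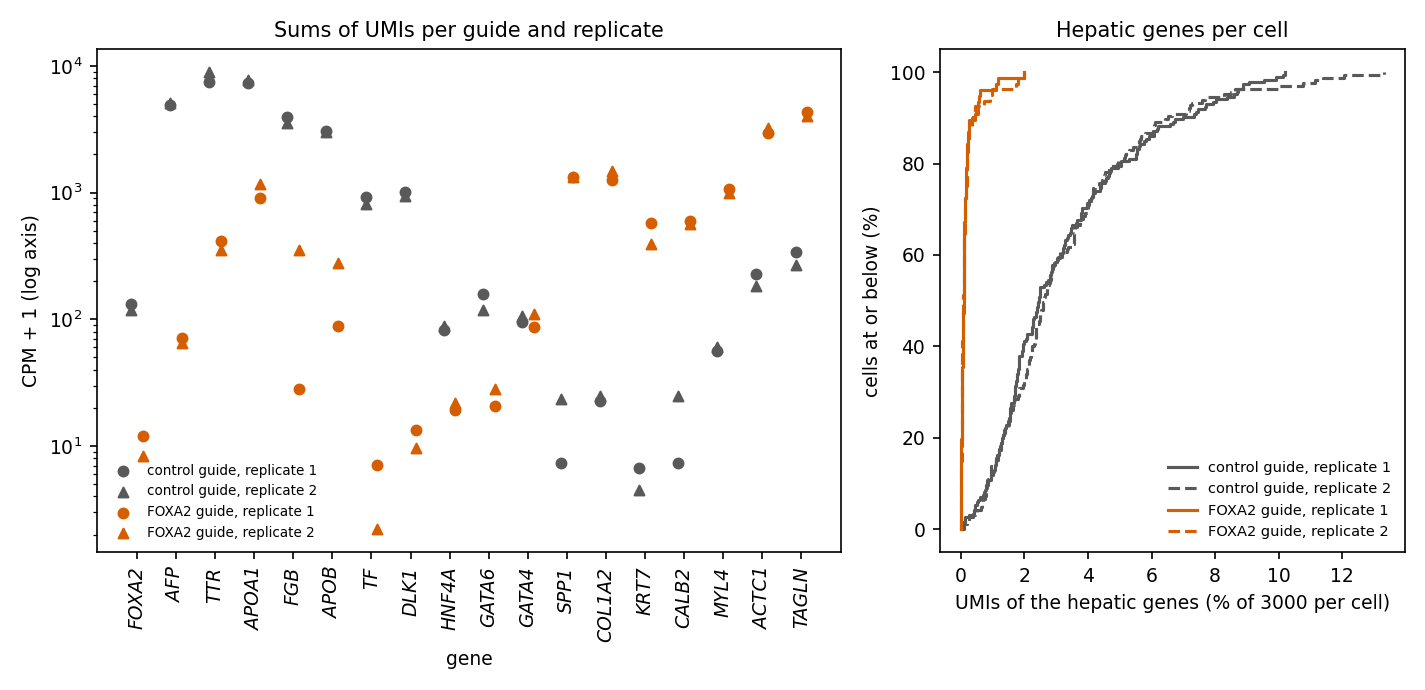
Left, CPM plus 1 on a log axis of 18 genes in sums of control-guide and FOXA2-guide cells, with a point per replicate; right, the cumulative share of cells against the percent of 3000 UMIs per cell that came from hepatic genes. AFP lies near 5000 CPM with the control guide and at 67.0 CPM with the FOXA2 guide, and 96.1% and 96.2% of FOXA2-guide cells have under 1% hepatic UMIs.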

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

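The tests in this part were chosen after the results were seen. Guides other than the 2 compared in the report appeared in hepatic endoderm cells, in data that no comparison used. FOXA2 guide 3 had UMIs in 82 cells of replicate 1 and 116 of replicate 2, although it had no count in genomic DNA of definitive endoderm. TGIF2 guide 3 had UMIs in 29 and 21 cells, of which 27 and 21 also held control guide 1, and USF1 guide 1 in 10 cells of replicate 2, all of which held control guide 1.

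For FOXA2 guide 3, all 198 cells with it also held control guide 1, where 71.2 cells without it would be expected if the guides were independent, and 0 of the 419 cells without control guide 1 had it (a share of up to 0.716%). A guide that lowers FOXA2 is argued against: FOXA2 stood at 103 and 110 CPM in control-guide cells with guide 3 and at 120 and 115 CPM in those without, a log2 ratio of −0.138 (95% counting interval −0.328 to 0.045), while guide 2 cells had 10.6 and 7.35 CPM. There were 3.07 and 4.66 guide 3 UMIs per 100 control-guide UMIs. The UMIs of guide 3 may come from reads of control guide 1 assigned to it, a candidate source that was not tested on sequences. No biological explanation was tested.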

How the results depend on the processing

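Of the alternatives, sums thinned to equal depth, control cells matched in UMIs per cell and lists without day 0 replicate 1 were chosen after the data had been seen; for the changes below the cause was not tested unless stated. Results for single genes kept direction and side of the threshold in 5571 cases, lost the call in 714, gained it in 1, moved without a test in 36 and changed sign in 6. For RNA this tally covers genes called in the main fits. Genes not called there are left out, such as LHX1, whose estimate on day 1 turned positive without day 0 replicate 1. Summary counts stayed within 1.5 times the reported value in 72 cases and moved in 25.

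DESeq2 called 1604 genes for day 1 against day 0, 1245 for day 2 against day 1, 96 for day 3 against day 2, 2546 for day 3 against day 0, 3656 for genes changed over days 0 to 3, 14 screen targets and 998 genes with the FOXA2 guide. A test against a fold of 2 (glmTreat), stricter by construction, called 394, 382, 5 and 1131 genes for the day comparisons in that order. For day 3 against day 2, no low-count filter gave 711 genes and only the libraries of those days 799. With each library left out in turn, counts ran from 1739 to 3341 for day 1 against day 0, from 954 to 2536 for day 2 against day 1 and from 15 to 555 for day 3 against day 2. With an estimated correlation, 0 lists passed for day 3 against day 0 in place of 9.

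The replicate number as a block gave 2957, 1811, 43 and 4194 genes for the day comparisons. Deviations of same-numbered libraries from their group means correlated at −0.124, 0.001 and 0.079. With 2 libraries per day, and day 0 libraries unlike in depth and endoderm transcripts, these values cannot settle whether the numbers pair the libraries. Removing the replicate block in hepatic endoderm gave 3480 genes in place of 3710.

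Without day 0 replicate 1, estimates for day 1 against day 0 changed sign for SOX17 (7.02), PRDM1 (5.62), EPSTI1 (0.87) and VWF (0.49), fitted against 2 or fewer day 0 counts; SOX17 passed as a rise, while PRDM1, EPSTI1 and VWF lost their call (adjusted p = 0.0954, 0.593 and 0.84). The lowest values without a library were −4.41 (SOX17 day 1 against day 0), −3.47 (PRDM1 day 1 against day 0), −3.63 (EPSTI1 day 1 against day 0) and −3.65 (VWF day 1 against day 0). With the FOXA2 guide, COL3A1 changed sign without replicate 2 (−2.67, against 5.91 without replicate 1) and HMGCS1 without replicate 1 (0.015, against −0.718 without replicate 2), as values of the remaining replicate: 2 sums leave no residual degrees of freedom and no test. The other settings for hepatic endoderm gave 3328 genes with at least 2 guide UMIs, 4720 with the top guide at 80%, 3708 with RLE factors, 3534 without a filter, 3182 at equal depth and 2811 with matched control cells, and 17 to 19 lower hepatic genes (16 with DESeq2). Depth limits low genes most: the smaller day 0 library holds 1901872 counts.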

Other observations

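The tests of day 0 replicate 1, of depth and of the number of guides, and the contractile, amino acid and matrix gene lists, were chosen after the results were seen; the other tests were written before.

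With the FOXA2 guide, genes of the contractile apparatus were higher in hepatic endoderm. Of 17 measured members of a contractile list 16 rose, with a median log2 fold change of 2.61: the smooth muscle genes ACTA2 (4.74), TAGLN (3.79) and CNN1 (3.34), the cardiac and skeletal genes TNNT2 (4.35), MYL4 (4.18), ACTC1 (3.91) and ACTA1 (3.59), and MYL7 (3.48). TTN (−1.52) was the exception. TAGLN went from 304 ± 50.7 to 4182 ± 223 CPM and ACTC1 from 204 ± 32.8 to 3077 ± 192 CPM (SD, n = 2 sums each). The list was written from genes seen to rise, so its count is a description.

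Genes that respond to amino acid shortage were higher as well, 17 of 21 with none lower and a median of 1.81. This list and the matrix list were also written after the results were seen and had no set test, so their counts are descriptions. ASNS, asparagine synthetase, went from 60.0 ± 5.96 to 572 ± 7.76 CPM, and PSAT1 (3.20), of serine synthesis, the folate enzyme gene MTHFD2 (2.85), the tRNA synthetase gene WARS (3.41) and CHAC1 (4.05) rose, while AARS, SLC7A5, SESN2 and PSPH did not pass. ATF3, DDIT3, DDIT4 and TRIB3 are also on the stress list. Matrix genes split, with 7 of 13 higher, such as COL1A2 and COL5A2 (3.57), and 4 lower, such as LAMB1 (−1.25) and COL6A1 (−2.06).

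Genes higher with the FOXA2 guide are argued not to follow from 2 technical effects. The lowered genes freed 15.6% of scaled counts, which can raise all other genes by at most 0.245 on the log2 scale, while 768 genes rose at least 2-fold. Control-guide cells were also matched to FOXA2-guide cells in UMIs per cell (medians 7910 and 7981 against 7909 and 8162). The median log2 fold change of the 1856 higher genes, from CPM ratios with 5 CPM added, was then 107% of that over all cells. That is 0.801 against 0.748. Bootstrap draws of the matched cells alone, with the all-cell median held fixed, gave 102% to 115%. These genes were chosen in the same cells, and matching kept 87 of 88 and 90 of 92 FOXA2-guide cells. The value thus does not test the rises themselves, and argues only against greater depth of FOXA2-guide cells as their sole source. With fewer control cells 1361 of the 1793 higher genes tested there were still called. An effect of this guide outside its target, or growth from few founder cells, cannot be told apart from loss of FOXA2, since 1 guide had enough cells. Loss of FOXA2 stays an open biological explanation.

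Day 0 replicate 1 held endoderm transcripts that replicate 2 lacked, in 27 genes defined by their level in the later libraries and near absence from replicate 2. Lower depth of replicate 2 is argued against: with replicate 1 thinned to the same total, these genes summed to 5877 counts against 328, a ratio of 17.9. Choosing genes by near absence from replicate 2 can inflate that ratio, so its size is no estimate of the difference. These genes stood at a median of 18.4% of their day 3 level (range 8.08% to 44.9%) and T at 2.75% of its day 1 level. Reads of the later libraries analysed here, assigned to it, may account for part of it and stay open: 8 of the 27 genes lay outside the 99% counting interval under the mix of 6 libraries that left the fewest outside. Cells or RNA of later days mixed in before library preparation, and reads of a later library not analysed here, stay open too, because the spread against the mix was 2.64 times that between the day 2 libraries (bootstrap interval 0.782 to 4.62); no biological explanation was tested.

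A hypothesis that genes which rose from day 0 to day 3 fall more often with the FOXA2 guide was tested over 9500 genes. Of 2004 such genes 392 (19.6%) were lower with the guide, against 17.3% of the others, an odds ratio of 1.16 (95% interval 1.02 to 1.32; Fisher's exact test, two-sided, p = 0.0195, adjusted p = 0.026 over 4 tests). The direction was not particular to falling genes: the same set was also higher with the guide more often, 26.9% against 16.6% (odds ratio 1.85, 1.64 to 2.08), and genes that fell over the course were lower with the guide more often (1.58, 1.37 to 1.82). Genes that fell over the course were not higher with the guide more often, 18.3% against 18.8% (odds ratio 0.965, 0.828 to 1.12). Genes are not independent, so these p-values are too small. Calls in both comparisons also depend on how many counts a gene has, which these odds ratios do not account for.

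A second hypothesis, that guides of more highly expressed targets are scarcer in genomic DNA, was tested over 49 targets. Spearman's rho was 0.07 with expression on day 0 (permutation p = 0.631, adjusted p = 0.922) and −0.014 with expression on day 3 (p = 0.922, adjusted p = 0.922, permutation test). Pearson's r was −0.184 (permutation p = 0.205) and −0.198 (permutation p = 0.172), adjusted p = 0.205 for both, and −0.184 and −0.261 without the 2 farthest targets. Bootstrap intervals of rho ran from −0.229 to 0.387 and from −0.310 to 0.297, so neither a weak negative relation nor its absence can be told apart.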
